A study of Homo sapiens with 17 samples.

How the data were processed

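The series holds RNA-seq of 786-O cells, a human clear cell renal carcinoma line that lacks functional VHL, the ubiquitin ligase subunit that marks HIF alpha proteins for destruction. Per the labels' protocols, cells were infected with lentivirus carrying Cas9 and a single guide RNA (pLenti CRISPR-V2, packaged in 293T cells) and kept under antibiotic selection. Polyadenylated RNA was made into libraries with the TruSeq RNA v2 kit and sequenced as paired reads of 150 bases. The 17 libraries fall into 6 groups, taken from the treatment label: HIF2a sg4, HIF2a sg6 and a scrambled-guide control for the HIF2a experiment, and USP37 sg3, USP37 sg9 and a separate scrambled-guide control for the USP37 experiment. Each group has 3 libraries except the USP37 control, which has 2, numbered 2 and 3. The labels do not say whether the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The guide sequences and cut sites are not given in the sources used here.

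The authors deposited a single table of variance-stabilised values on a log2-like scale, corrected for batch, for 27315 genes named by symbol. The submitters' processing notes name cutadapt, STAR 2.5.2b, Salmon and DESeq2 and the genome build hg19, without giving their roles, order or the annotation. The batch variable and the correction tool are not given in the sources used here. The values themselves show part of it: for every gene the means over all libraries numbered 1, over those numbered 2 and over those numbered 3 were equal to within 6.4e-14, so a term for the replicate number had been taken out of the table. Because the table has no library 1 for the USP37 control, that correction was not balanced over groups, and an alternative with the same term in the fit was run for that reason. Read counts cannot be recovered from these values, so the depth per sample is unknown and no interval or floor that needs it is given. Values ran from 4.85 to 20.1, and 8023 genes held a single value in every library. The deposited log2 scale flattens towards its floor of 5.14, so a fold change of a weakly expressed gene is understated. No library duplicated another: the median absolute difference between 2 libraries of a group was 0.0986 to 0.239.

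Genes were tested where their mean over the 17 libraries was at least 1 log2 unit above the 1st percentile of gene means, which left 12484 genes. The 6 group means were fitted in a single linear model with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation and a mean-variance trend (11 residual degrees of freedom). That number ignores the replicate term already taken out of the values, so p-values of this fit tend to be too small. The fit with that term shared by both experiments has 9. The effects of the guides were contrasts within an experiment: the mean of both guides against their control, each guide against that control, and guide against guide. An interaction contrast compared the USP37 effect with the HIF2a effect, and a further contrast compared the controls of the 2 experiments, where control and experiment cannot be separated. Adjusted p-values are Benjamini-Hochberg within a contrast, and a gene is called at an adjusted p under 0.05. The median standard error of a log2 fold change was 0.10 for the mean of the HIF2a guides and 0.12 for the mean of the USP37 guides.

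Before the data were examined, 22 gene lists were fixed, and the 19 with at least 5 tested members were tested with camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Each list was tested again with camera at an estimated correlation and with fry, which asks whether the genes of a list move on balance in 1 direction and does not compare the list with other genes. The lists cover HIF2A and clear cell carcinoma targets, glycolysis and HIF1A-preferred targets, HIF pathway machinery, DNA replication, mitosis, p53 targets, type I interferon response, unfolded protein and integrated stress response, cholesterol synthesis, fatty acid synthesis and storage, mesenchymal and matrix genes, YAP/TAZ targets, NF-kB and inflammatory genes, NRF2 targets, nuclear-encoded respiratory chain, mitochondrially encoded genes, cytosolic ribosomal proteins, replication-dependent histones, immediate early genes, renal tubular identity, 293T markers and leukocyte markers. EPAS1 and USP37 are in no list. The genes lower and the genes higher with the HIF2a guides were tested with camera as 2 sets in the USP37 experiment, with Benjamini-Hochberg adjustment over both.

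Named genes follow a rule fixed with the design: 13 key genes of the HIF pathway and the study in both experiments, and for each experiment the 6 largest rises and 6 largest falls among genes called in the mean of the guides and in each guide alone in the same direction. The rule adds 5 genes lower and 5 higher in both experiments, 3 higher and 3 lower genes between guides, and up to 4 called members with the largest change per list. Clone names and unnamed loci were passed over, and not every gene under the rule is printed. Genes outside this rule are said to have been chosen after their values were seen.

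The code was tested on simulated values drawn for the 12484 real genes, with 100 genes changed by 0.5 and 100 by 1 on the log2 scale. For the HIF2a guides it recovered 82% and 99% of these, with 14 false calls, and for the USP37 guides 67% and 97%, with 10 false calls. A simulated shift of a single list was called in both comparisons, with 0 of the other lists called. The simulated genes varied independently of each other, so false calls of lists whose genes vary together were not measured. In the real values, 66 of the 84 ways to choose the HIF2a control libraries gave at least 5 passing lists.

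Alternatives fixed before the data were examined were no filter and a stricter filter (19292 and 10643 genes), each experiment fitted alone, the replicate number as a block, no trend, robust moderation, array weights, median centring, quantile normalization, a minimum log2 fold change of 0.5, an estimated inter-gene correlation, Spearman's rho for the correlation, and each library left out in turn. Array weights stopped before reaching their convergence tolerance. Alternatives added after seeing the data were a replicate block shared by both experiments, USP37 libraries numbered 1 left out, libraries far from their group removed, values adjusted for transcript length and GC content with and without the block, and chromosome medians taken out. Transcript length and GC content came from GENCODE 29 on GRCh38, and were found by symbol or an older symbol for 12269 (98.3%) of the tested genes. A chromosome was found for 12328 (98.8%). That build differs from the submitters' hg19, so it served only for these properties and no coordinates are given.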

Results

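RNA was profiled in 786-O clear cell renal carcinoma cells after CRISPR guides against HIF2a (gene symbol EPAS1), the transcription factor that accumulates when VHL is lost, or against USP37, a deubiquitinase. The series title names deubiquitination of HIF2a by USP37 in kidney cancer, so the comparisons ask which transcripts change when either gene is targeted and how far the changes coincide. There were 3 libraries each of HIF2a sg4, HIF2a sg6, their scrambled control, USP37 sg3 and USP37 sg9, and 2 libraries of the scrambled control of the USP37 experiment. Values are the authors' batch-corrected, variance-stabilised log2 values. The depth per library is unknown, and fold changes of weakly expressed genes are understated on this scale.

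EPAS1 mRNA was lower with both guides against it. The deposited value was 11.91 ± 0.13 (SD, n = 3) in the control, 9.54 ± 0.14 (SD, n = 3) with sg4 and 10.34 ± 0.20 (SD, n = 3) with sg6. The mean of the guides fell by 1.97 on the log2 scale (SE 0.10, limma adjusted p = 2.21e-12), and sg4 lowered it further than sg6 (difference 0.81, limma adjusted p = 0.000154). USP37 mRNA was 9.24 ± 0.13 (SD, n = 2) in its own control, 8.33 ± 0.10 (SD, n = 3) with sg3 and 8.13 ± 0.14 (SD, n = 3) with sg9. It fell by 1.00 (SE 0.14, limma adjusted p = 1.22e-05), and the guides differed by -0.20 (limma adjusted p = 0.304). Each target was also lower in the other experiment. EPAS1 fell by 0.72 (SE 0.12) with the USP37 guides (limma adjusted p = 6.6e-05). USP37 fell by 0.44 (SE 0.12) with the HIF2a guides (limma adjusted p = 0.00903), a call lost without control library 1 (adjusted p = 0.0625) or 2 (adjusted p = 0.0657) of that experiment and without the 3 libraries far from their groups (adjusted p = 0.156). A guide that cuts a gene need not lower its mRNA, and protein was not measured here.

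**Figure D1:**
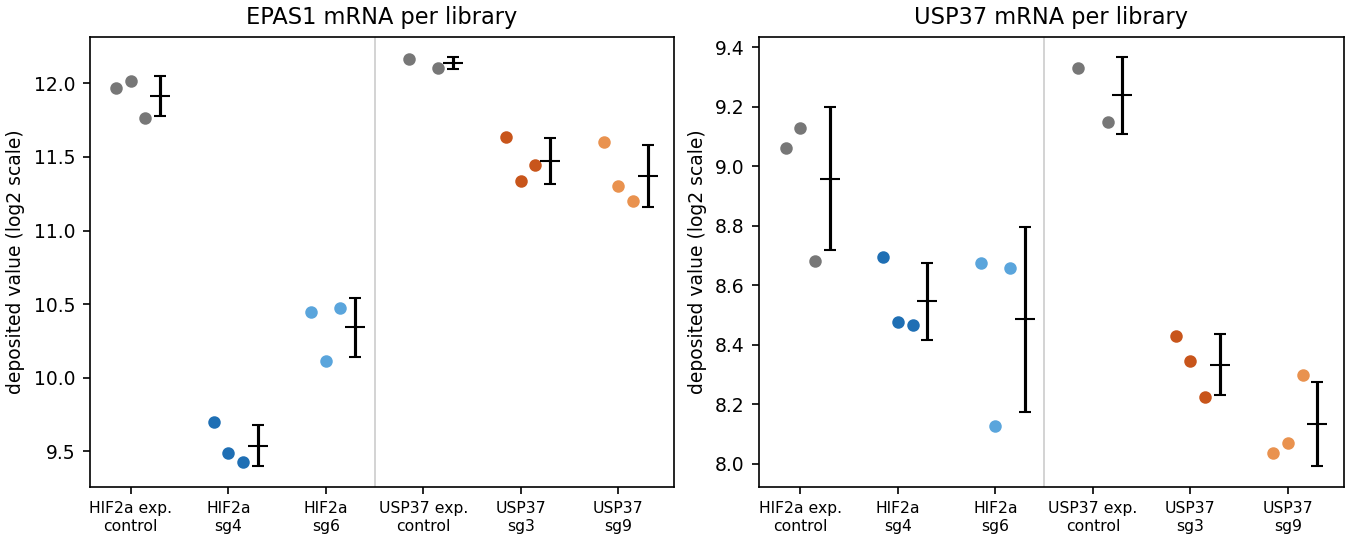
Deposited log2-scale value of EPAS1 (left) and USP37 (right) in each of the 17 libraries, by group; points are libraries, and the black mark gives the mean with its SD. EPAS1 was lowest with HIF2a sg4 (9.54) and sg6 (10.34), and USP37 was lowest with USP37 sg9 (8.13) and sg3 (8.33).

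With the HIF2a guides, the largest falls were CPE, a carboxypeptidase that processes prohormones (-4.44, SE 0.11), FLG, which encodes filaggrin (-4.05, SE 0.16), TMEM47 (-3.72, SE 0.14), the HIF prolyl hydroxylase EGLN3 (-3.72, SE 0.17), the semaphorin SEMA6A (-3.67, SE 0.15) and the ectonucleotidase ENPP3 (-3.66, SE 0.18). The largest rises were the chemokine CXCL12 (4.23, SE 0.15), TSPAN18 (3.19, SE 0.12), IGF2 (3.15, SE 0.12), TSPAN15 (2.95, SE 0.11), MXRA5 (2.76, SE 0.19) and PIGR, the polymeric immunoglobulin receptor (2.68, SE 0.12). These 12 genes had limma adjusted p-values from 1.93e-17 to 2.49e-10 and moved the same way within each of the 3 replicate numbers. For CPE (-2.10), FLG (-2.93), TSPAN18 (1.43), IGF2 (1.69), TSPAN15 (1.48), MXRA5 (1.85) and PIGR (1.21) the scrambled controls already differed. These values are the USP37 control minus the HIF2a control (limma adjusted p from 1.12e-09 to 7.61e-06), in the direction that would give the effect. CXCL12 differed the other way (-0.94), and TMEM47, EGLN3, SEMA6A and ENPP3 were not called. How far this adds to the changes stays open. IGF2 overlaps a readthrough gene with INS, so its reads may be shared. Among the key genes, HIF1A, the other HIF alpha subunit, rose by 0.90 (SE 0.09, limma adjusted p = 1.2e-07), while its partner ARNT (-0.08, SE 0.09, limma adjusted p = 0.547) and VHL (0.09, SE 0.09, limma adjusted p = 0.479) were not called. HIF1A was also higher in the USP37 control than in the HIF2a control (0.81, limma adjusted p = 2.5e-05). How much of its rise reflects a low value in the HIF2a control stays open. VHL lies on chromosome 3, whose genes were lower as a whole (median -0.22, 692 genes), and was called higher once chromosome medians were taken out (0.32, limma adjusted p = 0.00681). Over all genes, 2006 were higher and 1813 lower, of which 205 and 178 changed by at least 1 log2 unit. With both guides, 1128 genes were higher and 934 lower, and 16 were called in opposite directions.

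Targets of HIF2A had the lowest median of the 19 tested lists. Of the 26 tested members of the HIF2A and clear cell carcinoma target list, 18 were lower and 2 higher (19 and 2 adjusted over the list alone), with a median of -1.37 (camera adjusted p = 3.09e-18, and adjusted p = 0.0316 with an estimated correlation, or adjusted p = 0.0643 once length and GC content were also taken out, where the median was -1.43 and the preset camera adjusted p = 1.11e-17). EGLN3 (-3.72), the stress-responsive NDRG1 (-3.28) and the parathyroid hormone-like hormone PTHLH (-2.92) were among the largest falls. The growth factor TGFA (-2.42, SE 0.09), the glucose transporter SLC2A1 (-1.93, SE 0.09), cyclin D1 (CCND1, -1.64, SE 0.08) and VEGFA (-1.32, SE 0.12) also fell. PLIN2, a lipid droplet protein, was not called (SE 0.12, limma adjusted p = 0.983).

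**Figure D2:**
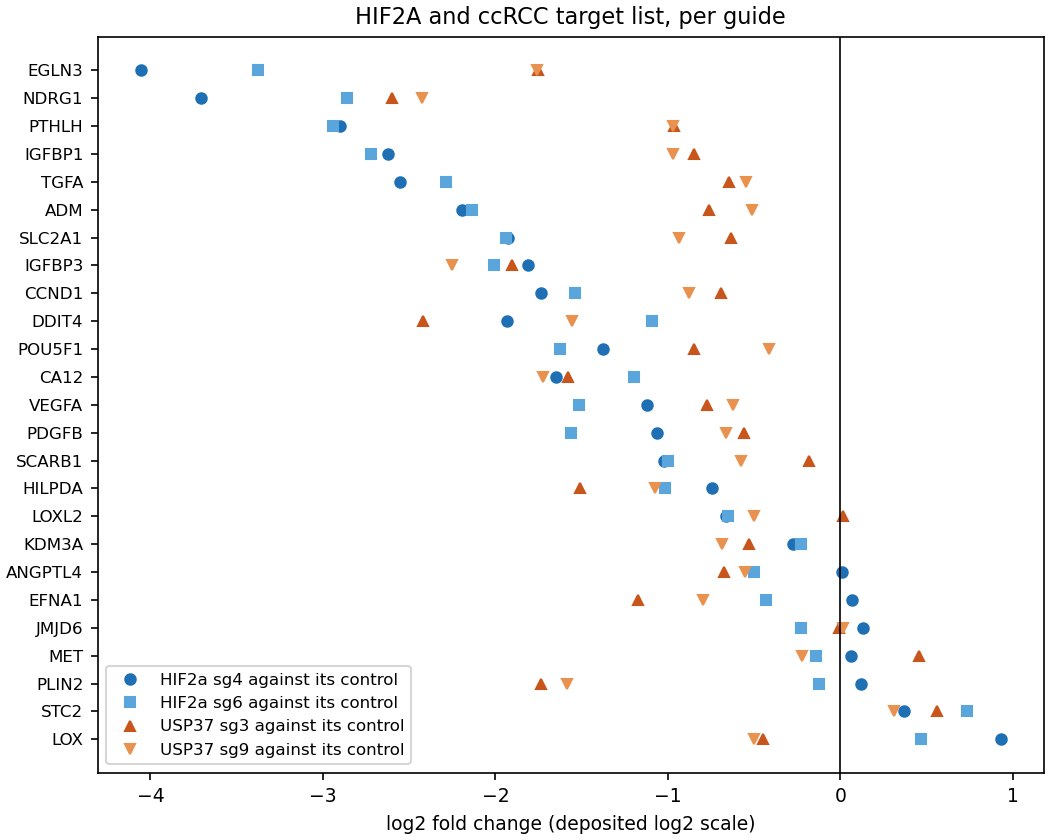
Log2 fold change against its own scrambled control for tested members of the HIF2A and clear cell carcinoma target list, with each of the 4 guides as a separate symbol. EGLN3 and NDRG1 lie below 0 with all 4 guides, and PLIN2 lies near 0 with the HIF2a guides and fell by 1.66 in the mean of the USP37 guides.

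p53 target genes were lower with the HIF2a guides in 14 of 24 members and higher in 2 (14 and 2 adjusted over the list alone, median -0.41, camera adjusted p = 3.46e-05, and adjusted p = 0.00617 with an estimated correlation). The cell cycle inhibitor CDKN1A (-1.79), ZMAT3 (-1.40) and the DNA repair factor DDB2 (-1.04) fell, while the cytokine GDF15 rose (1.77). The USP37 control minus the HIF2a control was 2.06 for GDF15 (limma adjusted p = 8.08e-08) and -0.33 for CDKN1A (limma adjusted p = 0.0116). Both differences have the direction that would give the effect. ZMAT3 and DDB2 were not called between the controls (limma adjusted p = 0.164 and 0.797). Type I interferon response genes were lower in 15 of 24 members and higher in 2 (17 and 5 adjusted over the list alone, median -0.44, camera adjusted p = 0.000126, and adjusted p = 0.0316 with an estimated correlation). IFI6 (-2.04), the antiviral enzyme RSAD2 (-1.39) and the ubiquitin-like ISG15 (-0.82) fell. BST2 (-0.73 in the mean of the guides) fell with sg6 (-1.31) and was not called with sg4 (-0.15, limma adjusted p = 0.417). All of these were higher in the HIF2a control than in the USP37 control. The USP37 control minus the HIF2a control was -3.24 for IFI6, -1.33 for RSAD2, -0.91 for ISG15 and -1.22 for BST2. Cholesterol synthesis genes were lower in 11 of 23 members and higher in 1 (12 and 1 adjusted over the list alone, median -0.23, camera adjusted p = 0.000222). They included MSMO1 (-1.42), INSIG1 (-1.30) and IDI1 (-0.71). That list's adjusted p = 0.373 with an estimated correlation. DNA replication genes were lower in 7 of 33 members and higher in 0 (7 and 0 adjusted over the list alone, median -0.13, camera adjusted p = 0.0171, and adjusted p = 0.786 with an estimated correlation), among them RRM2 (-0.68), E2F1 (-0.47), CCNE2 (-0.45) and MCM2 (-0.37). MCM2 also lies on chromosome 3 and was not called with chromosome medians taken out (limma adjusted p = 0.213). CCNE2 was not called without control library 1 (limma adjusted p = 0.127) or 3 (limma adjusted p = 0.0697). Without control library 3 the replication list had an adjusted p = 0.0519, without sg6 library 3 an adjusted p = 0.159, and without the 3 libraries far from their groups an adjusted p = 0.0874. The number of lists that pass is not by itself evidence of a HIF2a effect: 66 of the 84 ways to choose the 3 control libraries gave at least 5 such lists.

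The other 14 tested lists did not pass in the HIF2a experiment. Stress response genes had 11 members higher and 1 lower of 23 (camera adjusted p = 0.118), with CEBPB 0.66 and SDF2L1 0.65 higher and TRIB3 at -1.35. NF-kB and inflammatory genes had 9 higher and 3 lower of 20 (camera adjusted p = 0.127), with CX3CL1 at 0.84, SOD2 at 0.83 and CXCL1 at 0.72. CXCL1 was called with sg4 (1.35) and not with sg6 (0.09, limma adjusted p = 0.668). Fatty acid genes had 9 higher and 5 lower of 20 (camera adjusted p = 0.282), with DGAT2 at 1.36 and ACSL4 at 1.11 and LPIN1 at -0.63. Glycolysis and HIF1A-preferred targets had 7 higher and 6 lower of 22 (camera adjusted p = 0.978), with PFKFB3 at 1.49 and P4HA1 at -0.64. Immediate early genes had 7 higher and 8 lower of 18 (camera adjusted p = 0.863), with EGR1 at -1.82 and SPRY4 at 1.13. Mesenchymal and matrix genes had 6 higher and 5 lower of 24 (camera adjusted p = 0.863), with tenascin C (TNC) at 1.60 and TGFBI at -1.61. YAP/TAZ targets had 4 higher and 4 lower of 18 (camera adjusted p = 0.978), with tissue factor (F3) at -1.62. NRF2 targets had 5 higher and 3 lower of 18 (camera adjusted p = 0.692), with AKR1B10 at 1.64. AKR1C1 was at 1.91, and its reads may be shared with near-identical paralogs. Renal tubular genes had 5 higher and 4 lower of 14 (camera adjusted p = 0.692), with KRT19 at 1.65, EPCAM at 1.47 and CDH6 at 1.31 and the endopeptidase MME at -1.09. Respiratory chain genes (5 higher, 2 lower of 50, camera adjusted p = 0.485), ribosomal protein genes (1 higher, 7 lower of 50, camera adjusted p = 0.138), mitosis genes (0 higher, 4 lower of 26, camera adjusted p = 0.071), HIF pathway machinery (3 higher, 0 lower of 15, camera adjusted p = 0.408) and histones (0 higher, 0 lower of 6, camera adjusted p = 0.57) were also not called as lists. The ribosomal protein list passed without sg6 library 2 (adjusted p = 0.00258) or control library 2 (adjusted p = 0.00759), and the mitosis list without sg6 library 1 (adjusted p = 0.015), sg6 library 2 (adjusted p = 0.0396) or sg4 library 1 (adjusted p = 0.0429). The ribosomal protein list also passed with array weights (adjusted p = 0.02), with length and GC content taken out (adjusted p = 0.0387) and without the 3 libraries far from their groups (adjusted p = 0.000284). The mitosis list also passed with no filter (adjusted p = 0.0259), with array weights (adjusted p = 0.0116) and with chromosome medians taken out (adjusted p = 0.0175). The stress response list passed without sg6 library 2 (adjusted p = 0.0396). ARNT2 (1.14) was the largest rise in the HIF machinery list. The scrambled controls already differed at EPCAM (1.96), KRT19 (1.35), ACSL4 (1.11), PFKFB3 (0.89), AKR1C1 (0.74) and AKR1B10 (0.58). They also differed at SOD2 (0.53), TGFBI (-0.84), EGR1 (-0.83) and LPIN1 (-0.43). These values are the USP37 control minus the HIF2a control (limma adjusted p = 0.0153 or lower), in the direction that would give the effect. MME (1.37), ARNT2 (-1.35), P4HA1 (0.50) and TRIB3 (0.48) differed the other way, and the other named genes were not called. Adjusted over the list alone, the called members of each of these 14 lists in total stayed within 1.5 times these counts, except mitosis genes (2) and ribosomal protein genes (3). Median and mean differed in sign for the glycolysis, immediate early, YAP/TAZ, NRF2 and renal tubular lists, where the camera direction followed the mean except for glycolysis.

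The 2 HIF2a guides differed at 1151 genes, 607 higher and 544 lower with sg6 than with sg4. HS6ST2, a heparan sulfate sulfotransferase (3.21, SE 0.17), SAMD5 (2.37, SE 0.18) and FLG (1.47, SE 0.18) were higher with sg6, and BRINP2 (-1.49, SE 0.16) and TSPAN18 (-1.48, SE 0.13) were lower. The effects of the 2 guides correlated at r = 0.83 across genes, against 0.50 simulated for unchanged groups sharing those controls, with a covariance of 0.149 against 0.00915. The 3 control libraries cannot be split into parts of at least 2, so part of the excess may come from them. The independent overlap was 252.0 genes higher and 207.6 lower. The count of 1151 was 500 without sg4 library 2 and 612 without sg4 library 3. It was 413 without the 3 libraries that lay far from their groups, which are sg6 libraries 2 and 3 and control library 2, and the sg6 calls were then 2021 in place of 3624.

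USP37 guides lowered SEMA5B, a semaphorin (-3.37, SE 0.23), ENPP3 (-3.11, SE 0.20), the scaffold protein PDZK1 (-2.54, SE 0.16), FXYD2, a regulator of the sodium pump (-2.53, SE 0.21), NDRG1 (-2.51, SE 0.19) and LCN2, the siderophore-binding protein lipocalin 2 (-2.47, SE 0.17). They raised the keratin KRT81 (2.73, SE 0.12), SEMA7A (2.28, SE 0.17), IFI6 (2.19, SE 0.18), the kinase PLK2 (1.98, SE 0.15), PEG10 (1.86, SE 0.11) and the matricellular protein CTGF (1.80, SE 0.15). These 12 genes had limma adjusted p-values from 3.98e-12 to 1.25e-08 and moved the same way within both replicate numbers that have a control. For FXYD2 (1.67), NDRG1 (0.75), LCN2 (1.97), IFI6 (-3.24), PLK2 (-1.39) and CTGF (-1.12) the scrambled controls already differed. These values are the USP37 control minus the HIF2a control (limma adjusted p = 0.00817 or lower), in the direction that would give the effect. KRT81 differed the other way (1.28), and SEMA5B, ENPP3, PDZK1, SEMA7A and PEG10 were not called. FXYD2 overlaps a readthrough gene with FXYD6, and KRT81 has near-identical keratin paralogs, so their reads may be shared. ARNT fell by 0.98 (SE 0.10, limma adjusted p = 3.58e-07), and HIF1A was not called (-0.13, SE 0.11, limma adjusted p = 0.356). VHL was at -0.26 (SE 0.10, limma adjusted p = 0.0383), a call lost with the replicate block (adjusted p = 0.103), with each experiment fitted alone (adjusted p = 0.0527), and without control library 3 (adjusted p = 0.422), among other settings. Over all genes 2795 were higher and 2730 lower, of which 127 and 231 changed by at least 1 log2 unit. With both guides 1428 genes were higher and 1667 lower, and 33 were called in opposite directions. The control has 2 libraries, and without its library 2 the calls were 3683 in place of 5525, and those the same way with both guides 2025 in place of 3095. With a control library left out, the remaining one is assumed to vary like the other groups.

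HIF2A targets were also the list with the lowest median here. Of the 26 members 23 were lower and 1 higher (23 and 1 adjusted over the list alone, median -0.74, camera adjusted p = 3.45e-11, and adjusted p = 0.258 with an estimated correlation). NDRG1 (-2.51), IGFBP3 (-2.08), DDIT4 (-1.99) and EGLN3 (-1.75) fell most. PLIN2 fell by 1.66 (SE 0.14, limma adjusted p = 9.95e-09), and CCND1 (-0.79), SLC2A1 (-0.79), VEGFA (-0.70) and TGFA (-0.60) fell as well. YAP/TAZ targets had 11 higher and 2 lower of 18 (11 and 2 adjusted over the list alone, median 0.46, camera adjusted p = 0.00228, and adjusted p = 0.703 with an estimated correlation), with CTGF (1.80), CYR61 (1.70), the receptor AXL (1.14) and thrombospondin 1 (THBS1, 1.09). The USP37 control minus the HIF2a control was -1.12 for CTGF, -0.94 for CYR61, -1.11 for AXL and -0.72 for THBS1. These differences (limma adjusted p = 0.000325 or lower) have the direction that would give the rises. For ANKRD1, which rose by 1.01, the controls were not called as different (limma adjusted p = 0.945). THBS1 rose by 1.63 with sg3 and by 0.54 with sg9. Immediate early genes had 10 higher and 2 lower of 18 (11 and 2 adjusted over the list alone, median 0.49, camera adjusted p = 0.00228, and adjusted p = 0.258 with an estimated correlation), with FOSL1 (1.23) and the ERK phosphatases DUSP5 (1.15) and DUSP6 (1.03). Respiratory chain genes (31 higher and 1 lower of 50, 31 and 1 adjusted over the list alone, median 0.46) had a camera adjusted p = 4.69e-07, and adjusted p = 0.741 with an estimated correlation. Ribosomal protein genes (34 higher and 0 lower of 50, 35 and 0 adjusted over the list alone, median 0.38) had a camera adjusted p = 3.99e-07, and adjusted p = 0.741 with an estimated correlation. With length and GC content taken out, the medians were 0.28 for respiratory chain and 0.19 for ribosomal protein genes. NDUFB9 (0.99), UQCRH (0.96) and RPS25 (0.71) were among these. With sg3 alone, UQCRH (0.31, limma adjusted p = 0.103) and RPS25 (0.04, limma adjusted p = 0.851) were not called, against 1.61 and 1.39 with sg9. The respiratory and ribosomal medians were 0.10 and 0.024 with sg3 and 0.74 and 0.60 with sg9, so these rises lay mostly with sg9. No list passed with an estimated correlation in this experiment, and 10 of 19 passed fry.

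The other 14 tested lists did not pass with the USP37 guides. Type I interferon genes had 10 higher and 6 lower of 24 (camera adjusted p = 0.201), with IFI6 at 2.19, ISG15 at 1.08 and RSAD2 at 1.03. NF-kB and inflammatory genes had 7 higher and 7 lower of 20 (camera adjusted p = 0.871), with IL6 at 1.52 and CSF2 at 1.32 against BIRC3 at -1.87. Glycolysis genes had 4 higher and 10 lower of 22 (camera adjusted p = 0.113), with PFKL at -0.85 and PFKP at -0.59. DNA replication genes had 1 higher and 10 lower of 33 (camera adjusted p = 0.113), with MCM3 at -0.52 against CCNE1 at 0.67, and the list passed without control library 2 (adjusted p = 0.0258). Mitosis genes had 3 higher and 9 lower of 26 (camera adjusted p = 0.113), with TOP2A at -0.79 and BIRC5 at 0.55. Mesenchymal and matrix genes had 8 higher and 3 lower of 24 (camera adjusted p = 0.474), with TNC at 1.33 and SNAI2 at 0.84. Fatty acid genes (5 higher, 8 lower of 20, camera adjusted p = 0.263) included SCD at -0.86 and SREBF1 at -0.85, and NRF2 targets (3 higher, 6 lower of 18, camera adjusted p = 0.333) AKR1B10 at -1.89. Renal tubular genes had 5 higher and 5 lower of 14 (camera adjusted p = 0.871), with CDH16 at -1.76 against KRT8 at 0.70. p53 targets (5 higher, 7 lower of 24, camera adjusted p = 0.871) included GADD45A at 1.21. Stress response (7 higher, 5 lower of 23), cholesterol (4 higher, 5 lower of 23), HIF machinery (4 higher, 4 lower of 15) and histone genes (0 higher, 0 lower of 6) had camera adjusted p-values of 0.871, 0.845, 0.871 and 0.901. Adjusted over the list alone, the called members of each of these lists in total stayed within 1.5 times these counts. Median and mean differed in sign for the NF-kB, renal tubular and histone lists, where the camera direction followed the mean except for NF-kB. The 13 protein-coding genes of the mitochondrial genome were found in the table neither with nor without the MT- prefix, while its ribosomal RNAs were there as RNR1 and RNR2. Only NEFL of the 293T markers (-0.70 with the HIF2a guides, -0.68 with the USP37 guides) and only CSF1R of the leukocyte markers (-0.06 and 0.68) were expressed enough to test.

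The 2 USP37 guides differed at 3848 genes, 2071 higher and 1777 lower with sg9 than with sg3. The respiratory chain subunit NDUFA1 (1.98, SE 0.27), TMEM256 (1.79, SE 0.16) and S100A6 (1.67, SE 0.17) were higher with sg9, and CRIM1 (-1.16, SE 0.10), MAP1B (-1.11, SE 0.20) and fibrillin 1 (FBN1, -1.10, SE 0.22) were lower. Ribosomal protein genes had a median of 0.60 with sg9 (45 of 50 higher) and 0.024 with sg3, and respiratory chain genes 0.74 (40 of 50 higher) and 0.10. Both lists differed between the guides by camera (adjusted p = 1.65e-23 and 3.96e-19), not with an estimated correlation (adjusted p = 0.214 for each). In the same libraries the sg9 effect ran with transcript length across genes (Spearman rho -0.37), against rho -0.01 for sg3. With length and GC content taken out, the sg9 medians were 0.29 and 0.43. Genes are not independent replicates. Library 3 of sg9, with the highest median deviations from the gene mean over all libraries (0.69 for the ribosomal and 0.74 for the respiratory list), also stood apart in MALAT1 (10.10, against 12.97 and 13.37 in libraries 1 and 2) and RNR1 (14.42, against 16.28 and 16.18), both chosen after their values were seen. In libraries 1 and 2 these deviations were 0.48 and 0.57 for the ribosomal list and 0.51 and 0.63 for the respiratory list. The effects of the 2 guides correlated at r = 0.76, against 0.59 simulated for unchanged groups sharing those controls, with a covariance of 0.163 against 0.0129. The 2 control libraries cannot be split into parts of at least 2, so part of the excess may come from them. The independent overlap was 515.7 genes higher and 532.1 lower.

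**Figure D3:**
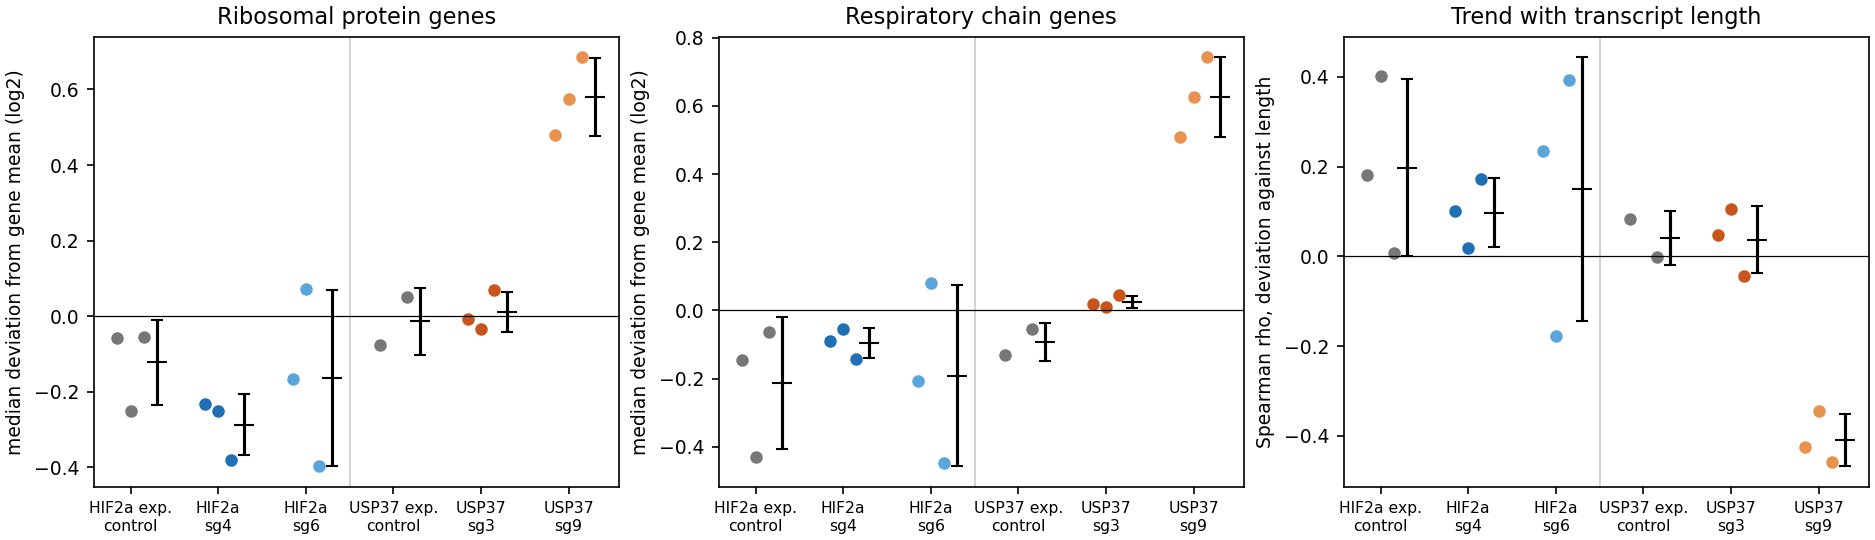
Median deviation from the gene mean (log2) of the ribosomal protein list (left) and the respiratory chain list (middle), and Spearman rho across genes between a library's deviations and transcript length (right), for each library by group. Points are libraries, and the black mark gives the mean with its SD; the 3 USP37 sg9 libraries lie at 0.48 to 0.69 in the left panel and at -0.46 to -0.34 in the right.

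Genes lower with the HIF2a guides were lower with the USP37 guides more often than independent lists would give. ENPP3 (-3.66 with the HIF2a guides and -3.11 with the USP37 guides), SEMA5B (-2.64 and -3.37), NDRG1 (-3.28 and -2.51), the complement regulator CFI (-2.16 and -2.07) and the sodium pump subunit ATP1B1 (-2.17 and -2.07) were lower in both. SIGLEC15 (1.5 and 1.37), TNC (1.60 and 1.33), TNFRSF11B (2.02 and 1.26), KRT81 (1.26 and 2.73) and EMP1 (1.22 and 1.41) were higher in both. In all, 596 genes were lower in both, where independent lists would share 396.5 (odds ratio 1.96, Fisher's exact two-sided p = 5.79e-32, across genes). For genes higher in both the count was 456, against 449.1 for independent lists (odds ratio 1.02, Fisher's exact two-sided p = 0.682), and 278 without control library 1 of the HIF2a experiment or 289 without control library 3 of the USP37 experiment. Opposite calls were also unevenly spread, 543 higher with HIF2a guides and lower with USP37 guides (438.7 independent) and 308 the other way (405.9). Of the 178 genes that fell by at least 1 log2 unit with the HIF2a guides, 113 were lower and 20 higher with the USP37 guides, median -0.64. Of the 205 genes that rose by at least 1, 94 were also lower and 39 higher with the USP37 guides, median -0.24. At a cut of 2, 30 of the 39 fallen genes were lower and 2 higher, and of the 14 risen genes 4 were lower and 4 higher (median -0.007). As a set, all 1813 genes lower with the HIF2a guides had a median of -0.10 with the USP37 guides (camera adjusted p = 0.00182, and adjusted p = 0.233 with an estimated correlation), and the 2006 higher ones -0.03 (camera adjusted p = 0.289, and adjusted p = 0.533 with an estimated correlation). The lower set was not called without sg6 library 2 (median -0.0697, camera adjusted p = 0.0518), and was called with any other single library left out. Its fall was also smaller without the 3 libraries far from their groups, where sg6 keeps a single library. The higher set was called, as lower with the USP37 guides, without control library 1 of the HIF2a experiment (median -0.076, camera adjusted p = 0.0256) and with a minimum log2 fold change of 0.5 (median -0.11, camera adjusted p = 0.0208). Across all genes the effects correlated weakly (r = 0.09, rho = 0.06, -0.003 simulated), with a covariance of 0.0160 against -4.44e-05. The jackknife error of r over libraries was 0.081, and r ran from 0.050 to 0.141 with a library left out, so it is not told apart from 0.

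**Figure D4:**
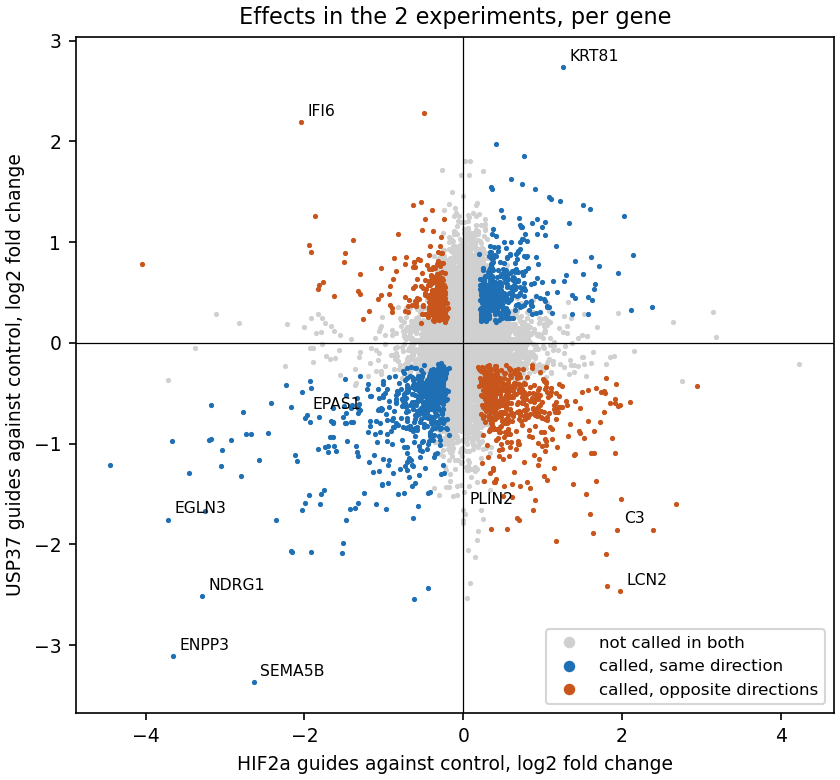
Log2 fold change of each of the 12484 tested genes with the HIF2a guides (horizontal) and the USP37 guides (vertical), each against its own control, in log2 units. Blue points were called in the same direction in both experiments (596 lower, 456 higher), orange points in opposite directions, and labels mark selected genes.

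The size of the effect differed between the experiments for several HIF targets. By the interaction contrast, the fall was larger with the HIF2a guides for EGLN3 (difference 1.96, limma adjusted p = 4.74e-06), TGFA (1.83, limma adjusted p = 4.35e-09), SLC2A1 (1.15, limma adjusted p = 1.74e-06) and CCND1 (0.85, limma adjusted p = 3.13e-05). It was larger with the USP37 guides for PLIN2 (-1.66, limma adjusted p = 4.48e-07) and ARNT (-0.90, limma adjusted p = 3.4e-05). PLIN2 also differed between the controls, by 1.91 in favour of the USP37 control (limma adjusted p = 1.79e-08), as did ARNT by 0.33 (limma adjusted p = 0.0267). CCND1 was lower in the USP37 control (-0.61, limma adjusted p = 0.00019). Each of these differences has the direction that would give the gene's interaction. The controls were not called as different for EGLN3, TGFA and SLC2A1 (limma adjusted p = 0.332, 0.735 and 0.608). ENPP3 (limma adjusted p = 0.114), CFI (limma adjusted p = 0.789) and IGFBP3 (limma adjusted p = 0.51) were not called as different. In all 4825 genes differed, 2448 in the positive and 2377 in the negative direction.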

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

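The tests of an effect shared by both USP37 guides and of the GC, length and replicate-number explanations for the HIF2A target list were chosen only after the result was seen. The longest transcript of a gene was used as its length at the start, and the principal transcript replaced it after the longest gave an implausible length for ribosomal protein genes. The control sets below replaced random draws of splits, which had been seen.

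By a test of the difference between the experiments, 4825 genes responded differently to the USP37 and the HIF2a guides, and 851 genes were called in opposite directions. The camera test of the same difference, USP37 effect minus HIF2a effect, passed for 9 lists, and for none of them with an estimated correlation. The median difference was 0.52 for HIF2A and clear cell carcinoma targets, 0.38 for p53 targets, 0.59 for type I interferon genes, 0.26 for cholesterol synthesis, -0.23 for fatty acid genes and 0.51 for YAP/TAZ targets. It was 0.37 for respiratory chain genes, 0.46 for ribosomal protein genes and 0.25 for immediate early genes.

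Between the HIF2a guides, sg6 minus sg4, 10 lists differed by camera, and 3 of them with an estimated correlation. The median difference was -0.40 for NF-kB and inflammatory genes (adjusted p = 0.00911 with an estimated correlation), 0.33 for NRF2 targets (adjusted p = 0.0076) and 0.29 for cholesterol synthesis (adjusted p = 0.0434). It was -0.35 for mitosis genes, 0.21 for fatty acid genes, -0.21 for mesenchymal and matrix genes, -0.17 for type I interferon genes, 0.15 for YAP/TAZ targets, 0.12 for glycolysis genes and 0.091 for ribosomal protein genes.

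Between the USP37 guides, sg9 minus sg3, 6 lists differed by camera and none with an estimated correlation (adjusted p from 0.214 to 0.405). The median difference was -0.18 for mitosis genes, -0.31 for mesenchymal and matrix genes, -0.47 for YAP/TAZ targets, 0.18 for NF-kB and inflammatory genes, 0.59 for respiratory chain genes and 0.60 for ribosomal protein genes.

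Ribosomal protein and respiratory chain genes were higher with sg9, and their medians with sg3 were 0.024 and 0.10, which argues against an effect shared by both USP37 guides. Short transcripts as a class were also higher with sg9, so a length bias of the libraries was tested against random lists matched on length and mean value, where the ribosomal median of 0.60 lay at percentile 99.97 (random lists reached 0.64) and the respiratory median of 0.74 at percentile 100 (random lists reached 0.66). After adjustment for length and GC content the medians were 0.29 and 0.43 and passed camera at the preset correlation (adjusted p = 1.17e-05 and 4.13e-08), not at an estimated one (adjusted p = 0.49 and 0.387). Both lists lay at or near the top of the matched lists, and the adjustment takes away a large part. Those random lists were drawn gene by gene, so they cannot stand for lists whose members vary together. Length as the whole cause is therefore not excluded. The matching was incomplete for ribosomal genes, whose random partners were longer (1249 against 959.5 bases) and had a lower mean value (12.70 against 13.30). An effect of sg9 alone, through USP37 or another site, and a difference in how these 3 libraries were grown or prepared both stay open as untested. MALAT1 and RNR1 set apart only library 3. The lists were also higher in libraries 1 and 2 (deviations 0.48 and 0.57 for ribosomal, 0.51 and 0.63 for respiratory genes). MALAT1 and RNR1 are thus no sign of a difference shared by the 3 libraries.

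HIF2A targets were lower with the USP37 guides (median -0.74). The tables argue against GC and length bias (median -0.77 after adjustment) and against the removal of the replicate number (median -0.78 with that term in the fit). The median also lay below those of random lists of this level (percentile 0, the lowest of 10000 random lists at -0.34). Those lists were drawn gene by gene, so they cannot stand for a list whose members vary together. With an estimated correlation the list was not called before the length and GC adjustment, and had a camera adjusted p = 0.193 after it. Lower EPAS1 mRNA (-0.72), an effect of USP37 on HIF2a protein, and a difference between the 2 control libraries and the guide cells unrelated to USP37 all stay open, and none can be separated by these values. An effect through HIF2a is a hypothesis that these values may fit. All 18 members called lower with the HIF2a guides were also called lower with the USP37 guides, and STC2 was higher in both. LOX goes against it, higher with the HIF2a guides (0.70) and lower with the USP37 guides (-0.47). PLIN2 (-0.00 and -1.66) was called only with the USP37 guides and differed by the interaction (limma adjusted p = 4.48e-07), though its controls differed too. EFNA1 (-0.18 and -0.98), ANGPTL4 (-0.25 and -0.62) and KDM3A (-0.25 and -0.61) were also called only with the USP37 guides. With the HIF2a guides, EFNA1 (0.07 with sg4, -0.43 with sg6) and ANGPTL4 (0.01 with sg4, -0.50 with sg6) had a negative mean only through sg6. KDM3A (-0.27 with sg4, -0.23 with sg6) narrowly missed in the mean of these guides (limma adjusted p = 0.0586). Whether EFNA1, ANGPTL4 and KDM3A go against the hypothesis stays open. Of these, STC2, LOX, EFNA1, ANGPTL4 and KDM3A were chosen after their values were seen.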

How the results depend on the processing

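The alternatives with the shared block, the balanced USP37 experiment, the removed libraries, the adjustments and the chromosome medians were chosen after seeing the data. No called result reversed its direction. Over the planned and added alternatives that do not leave out a library, 235 of 254 values of the main results stayed the same, as did 267 of 272 with a library left out. The same means within 1.5 times for a count, the same side of the threshold for a test, and a change below the jackknife error of 0.081 for the correlation. The fold change of EPAS1 ran from -2.05 to -1.87 and that of USP37 from -1.09 to -0.87. Of 243 named genes and lists, 240 kept their side with the replicate block. Because the authors had taken the replicate number out of the values, whether the numbers pair the libraries cannot be read from them, and the block changed no count of calls within an experiment by over 1.5 times (3384 calls with the HIF2a guides and 5073 with the USP37 guides). The interaction cannot be had with each experiment fitted alone.

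A minimum fold change of 0.5 leaves fewer genes by construction: 1405 with the HIF2a guides, 1499 with sg4, 1623 with sg6, 515 between them, 2652 with the USP37 guides, 2467 with sg3, 3550 with sg9, 1415 between those guides and 326 called the same way in both experiments. It raised the share of higher calls between the USP37 guides from 53.8% to 67.0%. Median centring and quantile normalization lowered that share to 47.7% and 48.2%, so the balance of directions between these guides depends on the scaling, and median centring raised the share between the HIF2a guides from 52.7% to 60.8%. Array weights gave 5150 calls with sg4 and 573 between the HIF2a guides, and quantile normalization gave 8 lists with the USP37 guides, adding the glycolysis, replication and mitosis lists (adjusted p = 0.043 each). Length and GC adjustment gave 1747 calls between the HIF2a guides. For these the cause was not tested. Quantile normalization fixes FN1 at 0 by construction, since it is the highest gene in every library.

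With an estimated correlation, which widens the test, 3 lists passed with the HIF2a guides and 0 with the USP37 guides, and the genes lower with the HIF2a guides (median -0.10 in the USP37 experiment) had an adjusted p = 0.233. Without the 3 libraries far from their groups, where sg6 keeps a single library assumed to vary like the other groups, sg6 gave 2021 calls and the HIF2a guides differed at 413 genes. The set's median was then -0.063 (camera adjusted p = 0.137). With a single library left out, its median ran from -0.154 (without control library 3 of the HIF2a experiment) to -0.0697 (without sg6 library 2, camera adjusted p = 0.0518), and only the latter was not called. The adjustment over the lower and the higher set was added after the data were seen.

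With each library left out in turn, calls ran from 2653 to 3963 with the HIF2a guides, from 3683 to 5854 with the USP37 guides (the lowest without USP37 control library 2) and from 500 to 1593 between the HIF2a guides (500 without sg4 library 2 and 612 without sg4 library 3). The lists that passed ran from 4 to 8 with the HIF2a guides (8 without sg6 library 2) and from 5 to 6 with the USP37 guides. Removing a control library leaves fewer samples (a single one for the USP37 control, assumed to vary like the other groups), and the cause was not tested further. Depth is unknown, so its limit on weakly expressed genes cannot be stated.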

Other observations

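The tests of chromosome 3 dosage and the opposite genes below were chosen only after the result was seen.

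Some of the largest effects ran in opposite directions in the 2 experiments. Higher with the HIF2a guides and lower with the USP37 guides were LCN2 (1.97 and -2.47), the complement component C3 (1.94 and -1.85), the immunoglobulin receptor FCAMR (2.40 and -1.86), the matrix protease MMP7 (1.81 and -2.41), the aldo-keto reductase AKR1B10 (1.64 and -1.89) and the acute phase gene SAA2 (1.80 and -2.09), whose reads may be shared with a near-identical paralog. Lower with the HIF2a guides and higher with the USP37 guides were IFI6 (-2.04 and 2.19), RSAD2 (-1.39 and 1.03), IGFBP5 (-1.86 and 1.26), TENM2 (-1.94 and 0.97), GALNT5 (-1.91 and 0.90) and SLAMF8 (-1.49 and 0.89). The interaction had limma adjusted p-values from 2.62e-13 to 1.6e-08 for these 12 genes, and all 4 guides had the direction of their pair. The controls already differed at all of them except SAA2 (0.14, limma adjusted p = 0.543), in the direction that would give opposite effects. The USP37 control minus the HIF2a control was 1.97 for LCN2, 2.36 for FCAMR, 1.20 for C3, 1.11 for MMP7 and 0.58 for AKR1B10. It was -3.24 for IFI6, -3.34 for IGFBP5, -1.33 for RSAD2, -1.63 for TENM2, -0.61 for GALNT5 and -1.41 for SLAMF8. These differences were smaller than the difference between the effects (-4.44 to -3.53 for the first 6 genes, 2.38 to 4.23 for the others) for every gene except IGFBP5 (3.12), whose controls differed by as much within the error. The genes were picked for the size of their opposite effects, so how far a difference between the controls explains opposite calls stays open.

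The scrambled controls of the 2 experiments differed at 5051 of 12484 genes (2290 in the fit with the replicate block), PLIN2 among them. Experiment and control cannot be separated here, so an effect of one experiment is read only against its own control.

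Chromosome 3 genes were lower with both HIF2a guides (median -0.22 over 692 genes, 289 called lower and 36 higher, against 0.006 for genes on the other chromosomes). Adjustment for GC content and length left the median at -0.19, and of 10000 random gene sets of that size the share with a median as far from that of all genes was 1e-04, the smallest that many sets can give, which argues against both a bias of this kind and chance placement. Chromosome 3 was not alone: chromosome 13 had a median of -0.19 (35.7% of its genes called lower and 6.8% higher, median -0.14 after adjustment), and chromosomes 14, 16, 17 and 22 had medians of 0.12, 0.12, 0.12 and 0.13. All 17 runs of 40 neighbouring genes had a median below 0 with both guides, so the fall was spread along the chromosome. With a chromosome median of -0.22 most runs are likely to lie below 0, and the guides share their control libraries. The count thus cannot tell a copy change from another broad shift. A candidate explanation, written as a hypothesis, is that the control cells and the guide cells differ in the copies of chromosome 3 they carry, and with both USP37 guides 5 of the 17 runs were below 0. The scrambled controls differed little on chromosome 3 (median -0.04, USP37 control minus HIF2a control), while sg4 and sg6 both lay lower (-0.22 and -0.23). On chromosomes 13 and 14 the controls themselves differed (medians 0.24 and 0.23). DNA was not measured here, and a HIF2a effect spread over this chromosome stays open as untested.

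For the HIF2a experiment, 84 sets of 3 control libraries were each tried once, without those that only mix the guides. The real set gave 3819 calls, and only it reached that count (1 of 84, highest other 2479, with the sg6 libraries as controls). A random choice of control libraries is thus an unlikely source of that count. The sets cannot exclude a chance difference between the control and the guide cultures, since the replicates may be technical. The HIF2A target median of -1.37 was also reached only by the real set (1 of 84, lowest other -0.76). The number of lists that passed, 5, was reached by 66 of the 84 sets (highest other 11), so chance cannot be excluded for it. For 3 against 3 libraries there are 10 splits, too few for a share under 0.05: sg4 gave 3159 calls (highest other 0), sg6 3624 (highest other 571), sg6 against sg4 1151 (highest other 0) and sg9 against sg3 3848 (highest other 0), each by 1 of the 10 splits.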
